A study of Homo sapiens with 98 samples.

How the data were processed

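Labelled RNA of HepG2 cells exposed to copper sulfate and of untreated cells was hybridised together on 98 Agilent 2-colour arrays. The labels give 4 doses and 4 times, and for every array which dye carried the treated RNA. Per the labels the control was untreated cells of the same time, while the series text speaks of a common pool of untreated cells, so it stays open whether times share a control. Titles and series text give the doses in µM and are followed here, although one protocol text reads mM.

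Per the labels' protocols, 3 sets of RNA were prepared for each condition and each was hybridised in both dye orientations, and the authors normalised with LOWESS in GeneSpring. The deposited scanner files hold, per the file headers, mean and background intensity values in red and green from Agilent Feature Extraction, with a log10 ratio of red over green. The values deposited in the series matrix are the authors' processed ones, normalised by the authors with LOWESS per the labels and, set against the scanner values, a natural log of treated over control. Their slope on the scanner's log2 ratios had a median of 0.65 and ran from 0.535 to 0.687, where the change of log base alone gives 0.693, and their correlations with these ratios across probes lay between 0.773 and 0.990. Of these values 9.06% were missing and 1471 lay at a floor of -4.605, and column medians lay between -0.034 and 0.0221.

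Background was corrected with normexp (offset 50) on mean signals and local median backgrounds and each array was normalised with loess in limma 3.58.1 under R 4.3.3, with data.table (version 1.17.8) for file handling. Control spots had weight 0 in the loess and were then left out, and outlier spots were set to missing, at most 1.49% of spots per array. All ratios were turned to log2 treated over control. Within each group the lowest-numbered array with treated RNA in Cy5 was averaged with the lowest-numbered one in Cy3, and so on, which made 49 pairs. The labels do not state which arrays share RNA. If a pair joins different sets, a set can enter more than 1 pair. The SD and p over pairs may then understate the spread between sets. The 8 arrays at 400 µM for 4 h make 4 pairs where 3 sets would make 3, so 1 pair there may repeat a set of RNA and n = 4 may overstate the replication. Over all 49 pairs the arrays of 16 correlated above 0.1 in their deviations (median -0.164), and of 6 and 5 with the partners rotated (medians -0.322 and -0.416), so most pairs gave no sign of shared RNA. Among the 12 late pairs at high dose all did (median 0.402), against medians of -0.476 and -0.4635 with the partners rotated. The 3 sets may be technical or biological replicates, and the test of a ratio against 0 leaves out the control's own spread.

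Of 20173 gene probes 19986 were kept, those well above background in either channel on a share of at least 0.5 of the arrays of a group. They stand for 18330 genes, each given by its brightest kept probe. Probes were named through accessions in the RefSeq gene list (14329 probes), through the file's newer name (549) or older name (1748), and 3547 kept the file's name. Where both routes gave a symbol, 9516 of 9609 were the same. ASNS is named through the older name only. Probes of one gene disagreed for HSPA1A, MT1M, TMT1A, H2AC18, HMGCS1, PSMD12, RPLP1, BBC3, TNFRSF10B and CACNA2D4 among those named. Metallothioneins, HSPA1A and HSPA1L, HP and HPR, and VCX and VCX3A are close in sequence, and their probes may take up each other's RNA.

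One limma model with a mean per group and an intensity trend in the moderation was fitted to all pairs. Each group was tested against 0, the slope over dose within each time, 24 h against 4 h within each dose, and the slope at 24 h against that at 4 h. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 size of at least 1. The 26 gene lists, fixed before the data were examined together with the tests, the alternatives and the rule for named genes, were tested with camera at a preset correlation of 0.01 over genes complete in all pairs, with adjustment over all lists and groups. A list count adjusted over the list alone applies the adjustment among its members only. The lists were metallothioneins, copper handling, zinc transporters, iron handling, cytosolic heat shock, NRF2, ATF4, endoplasmic reticulum chaperones, proteasome, p53, apoptosis, immediate early, inflammatory, mitosis, DNA replication, histone, cholesterol, fatty acid, secreted liver, liver enzyme, hypoxia, lipoylation, complex IV, ribosomal, stromal and blood genes.

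Named genes are, for each time at 600 µM, the 8 largest rises and 8 largest falls among called genes with the same sign in every pair and brighter than background on most arrays, the 3 each way at each lower dose, the 3 each way for every trend and time difference, and members of the lists. From the smallest change upward some were left out. A spot saturated in the treated channel on every array of a group gives only a bound, written as at least N-fold. It is the mean treated level against the mean control level after loess and between-array scaling (Aquantile), open to dye bias only where dye swaps are unbalanced.

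Alternatives were no background correction, median centring without loess, the scanner's log ratios, the authors' processed values, no filter and a stricter filter on dim probes, the mean of a gene's probes, moderation without a trend, other pairings, single arrays with a dye term, each orientation alone, pair number as a block, day of image extraction as a fixed or random block (correlation within day 0.072), leaving out each pair, and for lists an estimated correlation and fry. After the data were seen, fits without the 400 µM groups, a list test of the time difference and a list test with missing values filled were added. The limma and camera steps were tested on simulated data with 200 changed genes among 18330. For 600 µM at 4 h, 98% of genes changed by 1.2 in log2 and 100% of those changed by 1.5 were recovered, and 0% at 0.8. For the trend at 12 h the shares were 98%, 100% and 0%, for 24 h against 4 h at 200 µM 98%, 100% and 4%, and for the difference of trends 90%, 100% and 6%, with 0 false calls in each. The simulated noise was independent between pairs. False calls from a shared control, a day or a set of RNA in 2 pairs were therefore not covered.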

Results

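HepG2, a human liver tumour line that keeps many hepatocyte functions, was exposed to copper sulfate at 100, 200, 400 or 600 µM for 4, 8, 12 or 24 h. Messenger RNA was measured on 98 Agilent 2-colour arrays, each with RNA of treated cells in one dye and of untreated cells in the other. The 16 combinations of dose and time had 6 arrays each, except 400 µM for 4 h with 8, and each group held equal numbers of arrays with the treated RNA in Cy5 and in Cy3. Arrays of opposite dye were averaged into pairs, so n = 3 pairs per group and n = 4 at 400 µM for 4 h, where the 3 sets of RNA that the labels' protocols state leave open whether 1 pair repeats a set. Between 76.4% and 98.2% of probes per array were well above background in the treated channel, and between 74.7% and 98.1% in the control channel. The number of arrays limits the precision. The comparisons ask how far transcript levels moved at each dose and time, how they moved with dose, and whether the response at 24 h differed from that at 4 h. Log2 values are treated over control, as mean ± SD over pairs.

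At 100 µM the metallothioneins, small cysteine-rich proteins that bind copper and zinc, rose at every time. MT1F rose by 2.86 ± 0.19 on the log2 scale (n = 2) at 4 h. MT1M rose by 2.63 ± 0.36 (n = 3) at 4 h, by 2.65 ± 0.38 at 8 h, by 2.88 ± 0.32 at 12 h and by 2.50 ± 0.37 at 24 h, and MT1F by 2.80 ± 0.11 (n = 3) at 24 h. Of 11 measured metallothioneins, 9 rose at 4, 12 and 24 h and 8 at 8 h, and none fell. The counts adjusted over the list alone were the same, and the camera adjusted p of the list ran from 9.84e-32 at 12 h to 2.39e-65 at 24 h. ASNS, an asparagine-making enzyme under ATF4 control, was at 1.16 ± 0.53 at 4 h, 1.38 ± 0.07 at 8 h, 1.27 ± 0.54 at 12 h and 1.52 ± 0.26 at 24 h, past the test each time. In the ATF4 list 2 of 25 genes rose at 4 h and 1 at each later time, also adjusted over the list alone, with camera adjusted p from 1.71e-08 at 12 h to 1.01e-33 at 24 h. That at 12 h was not kept (adjusted p = 0.0908 with an estimated correlation). The 1 gene at each later time was ASNS, whose probe may take up metallothionein RNA, which stays open (see other observations). The ATF4 list was not tested without ASNS. HMOX1, the heme-degrading enzyme, rose by 1.62 ± 0.81 at 8 h and was at 0.94 ± 0.62 at 4 h, 0.96 ± 0.32 at 12 h and 0.41 ± 0.075 at 24 h without passing the test. In the NRF2 list of antioxidant genes 1 of 29 rose at 8 h and 0 at the other times, with camera adjusted p from 2.28e-06 at 4 h (adjusted p = 0.0705 with an estimated correlation) to 4.65e-52 at 24 h. Of 29 heat shock genes 1 rose at 8 h, HSPA6 at 1.07 ± 0.66, and 2 adjusted over the list alone (camera adjusted p = 0.000466, adjusted p = 0.162 with an estimated correlation). The limma test called 16, 15, 17 and 14 genes higher at 4, 8, 12 and 24 h and 0 lower. At an unadjusted p under 0.05 there were 2257, 2004, 2469 and 742 genes in either direction. The authors' processed values gave 23 higher and 4 lower at 4 h, 19 and 7 at 8 h, 23 and 3 at 12 h, and 14 and 7 at 24 h. With day of image extraction as a block the counts were 10 at 4 h, of which 8 were shared with the unblocked fit, 17 at 12 h and 14 at 24 h. The 8 h arrays all came from one day. Within a day, 17 genes passed at 4 h with 3 pairs, 3 at 12 h with 2 pairs and 13 at 24 h with 2 pairs. At 4 h these were all pairs of the group, so that count does not test day. The ASNS call at 4 h was lost without the third pair, at 0.99, and with day as a block, at 0.81. HSPA6 at 8 h was not past the test without the first pair (1.14) or the second (0.71). HMOX1 passed at 4 h without the first pair, at 1.28, and at 12 h without the first pair, at 1.09.

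**Figure D1:**
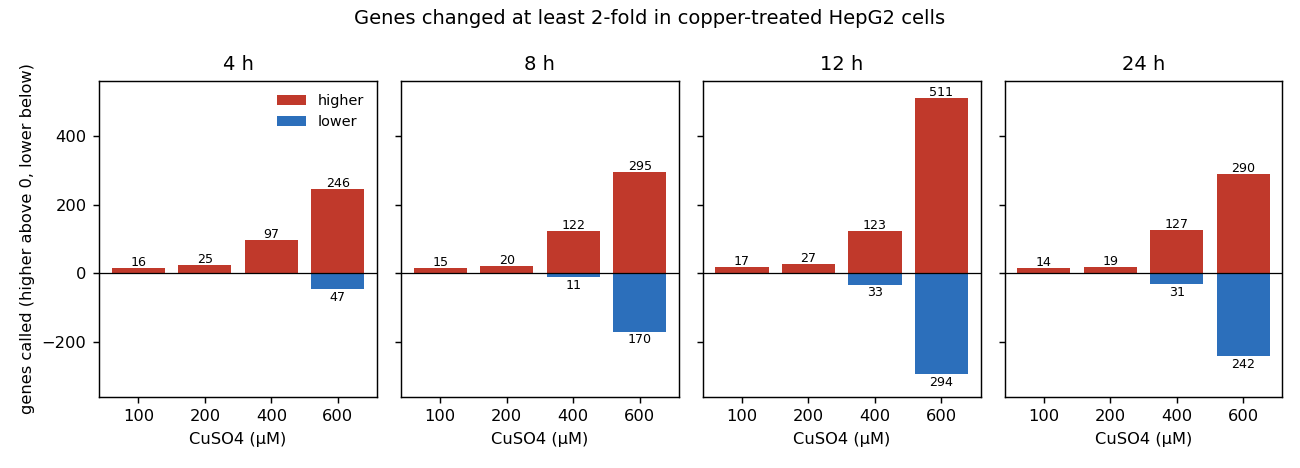
Number of genes called higher (above 0) and lower (below 0) than control at each copper dose (µM) and time (h), from the limma test; bars are counts over the genes tested in each group, between 18307 and 18330. The counts ran from 14 higher and 0 lower at 100 µM for 24 h to 511 higher and 294 lower at 600 µM for 12 h.

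At 200 µM the metallothioneins rose again. MT1M was at 2.99 ± 0.23 (n = 3) at 8 h. MT1F was at 3.14 ± 0.26 (n = 2) at 4 h, 2.84 ± 0.31 (n = 3) at 8 h, 3.54 ± 0.24 at 12 h and 3.71 ± 0.060 at 24 h. Of the 11, 9 rose at 4, 12 and 24 h and 8 at 8 h, also adjusted over the list alone (camera adjusted p from 1.38e-25 to 1.6e-35). EGR1, an immediate early transcription factor, rose by 1.36 ± 0.54 at 8 h, by 1.52 ± 0.37 at 12 h and by 1.98 ± 0.32 at 24 h. HMOX1 rose by 1.34 ± 0.20 at 4 h, by 1.95 ± 0.75 at 8 h and by 1.47 ± 0.43 at 12 h and was at 0.76 ± 0.044 at 24 h, not past the test. HSPA6, a stress-induced HSP70, rose by 1.86 ± 1.2 at 8 h and by 1.66 ± 0.24 at 12 h and stood at 0.17 ± 0.070 at 24 h. ASNS rose by 1.31 ± 0.43, 1.58 ± 0.047, 1.59 ± 0.26 and 2.14 ± 0.018 at 4, 8, 12 and 24 h. Of 29 heat shock genes, 2, 3 and 4 rose at 4, 8 and 12 h, also adjusted over the list alone. The list's camera adjusted p was 0.00973 at 8 h and 0.0109 at 12 h, neither kept (adjusted p = 0.311 with an estimated correlation at both times). In the ATF4 list 3, 1, 1 and 2 of 25 rose, with camera adjusted p from 5.33e-13 to 2.07e-38. ASNS was among them at each time, with the same doubt about its probe. In the immediate early list 3, 1, 2 and 1 of 23 rose, with camera adjusted p from 1.27e-06 to 1.81e-15. The call of the immediate early list at 8 h was not kept (adjusted p = 0.0668 with an estimated correlation). The limma test called 25, 20, 27 and 19 genes higher at 4, 8, 12 and 24 h and 0 lower, with 2528, 3768, 2891 and 3160 at an unadjusted p under 0.05. The authors' processed values gave 33 higher and 6 lower at 4 h, 26 and 15 at 8 h, 36 and 8 at 12 h, and 26 and 3 at 24 h. The day of the 4 h arrays was again linked to other days by 1 pair of this dose at 12 h alone. Blocking on day left 27 genes at 4 h (20 shared), 26 at 12 h (26 shared) and 21 at 24 h (19 shared). Within a day it was 25 at 4 h with all 3 pairs, which does not test day, and 24 at 12 h with 2 pairs. HSPA6 also passed at 4 h, at 1.35 ± 0.45, but not without the third pair (1.09) or with day as a block (1.5), and ASNS at 4 h was not past the test with day as a block (0.96).

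At 400 µM the response took in chaperones, antioxidant enzymes and early transcription factors. HMOX1 rose by 4.07 ± 0.34 (n = 4) at 4 h, by 4.34 ± 0.28 (n = 3) at 8 h, by 3.79 ± 0.29 at 12 h and by 3.02 ± 0.37 at 24 h. HSPA6 rose by 3.75 ± 0.32 (n = 4), 4.50 ± 0.52 and 3.85 ± 0.23 at 4, 8 and 12 h and stood at 0.74 ± 0.13 at 24 h, where the authors' processed values put it past the test at 1.84. HSPA1A was at 3.98 ± 0.074 (n = 4) at 4 h, saturated on 7 of 8 arrays. SLC30A1, the zinc exporter of the plasma membrane, rose by 2.00 ± 0.27 (n = 4) at 4 h and by 1.82 ± 0.34 at 8 h. MT1F rose by 3.67 ± 0.22 at 8 h, by 4.17 ± 0.72 at 12 h and by 4.84 ± 0.42 at 24 h. MT1M rose by 3.79 ± 0.29 (n = 4) at 4 h, by 4.07 ± 0.48 at 12 h and by 4.67 ± 0.21 at 24 h, and MT1E at 24 h was at least 19.5-fold higher with its treated spot saturated on all 6 arrays (adjusted p = 7.11e-20). CRYAB, a small heat shock protein, rose by 3.07 ± 0.26 at 8 h and by 3.92 ± 0.13 at 12 h, and EGR1 by 3.88 ± 0.083 at 12 h. Several genes made in the liver fell from 8 h on. SELENOP, a selenium carrier made by the liver, fell by 1.46 ± 0.35 on the log2 scale at 8 h and fell by 1.62 ± 0.28 at 12 h. The fibrinogen chain FGG fell by 1.5 ± 0.30 at 12 h and fell by 1.97 ± 0.20 at 24 h, FGA fell by 1.56 ± 0.31 at 24 h, and the erythropoietin gene EPO fell by 1.46 ± 0.14 at 8 h. These 4 fell in every pair. TMT1A, a thiol methyltransferase, fell by 1.61 ± 0.30 at 24 h at its brighter probe and was at -0.85 with the mean of its probes.

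Among the lists at 400 µM, 9, 11, 9 and 2 of 29 heat shock genes rose at 4, 8, 12 and 24 h, and 12, 11, 13 and 8 of 23 immediate early genes. In the NRF2 list 5, 10, 6 and 6 of 29 rose, among them GCLM at 2.56 ± 0.096 at 8 h, and in the ATF4 list 9, 7, 3 and 11 of 25, among them ASNS at 3.15 ± 0.34 at 24 h. Metallothioneins rose in number 9 of 11 at every time, while 3 of 34 secreted liver proteins fell at 12 h and 5 at 24 h. These counts were the same adjusted over the list alone. The camera adjusted p of the heat shock list was 1.67e-12, 1.39e-15 and 5.95e-08 at 4, 8 and 12 h and 0.851 at 24 h, and that of the secreted liver proteins 5.22e-07 at 12 h and 1.55e-09 at 24 h. The ATF4 list at 12 h had a camera adjusted p of 2.03e-07 (adjusted p = 0.122 with an estimated correlation), and the secreted liver proteins at 8 h one of 0.000774 (adjusted p = 0.138 with an estimated correlation). The limma test called 97 genes higher and 0 lower at 4 h (6187 in either direction at an unadjusted p under 0.05), 122 and 11 at 8 h, 123 and 33 at 12 h, and 127 and 31 at 24 h. The authors' processed values gave 124 and 37 at 4 h, 157 and 94 at 8 h, 219 and 104 at 12 h, and 253 and 138 at 24 h. The scanner's log ratios gave 172 and 44 at 8 h, 238 and 114 at 12 h, and 271 and 140 at 24 h, and median centring without loess gave 89 and 93 at 12 h. Without the second pair 172 genes were higher and 73 lower at 24 h, 245 in all. Under the day block 93 genes passed at 4 h (93 shared), 175 at 12 h (141 shared) and 143 at 24 h (135 shared). Within a day 156 passed at 12 h with 3 pairs and 146 at 24 h with 2 pairs. At 12 h these were all pairs of the group, so that count does not test day. The 4 h arrays came from days of their own, so their count under the block does not test those days against others.

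**Figure D2:**
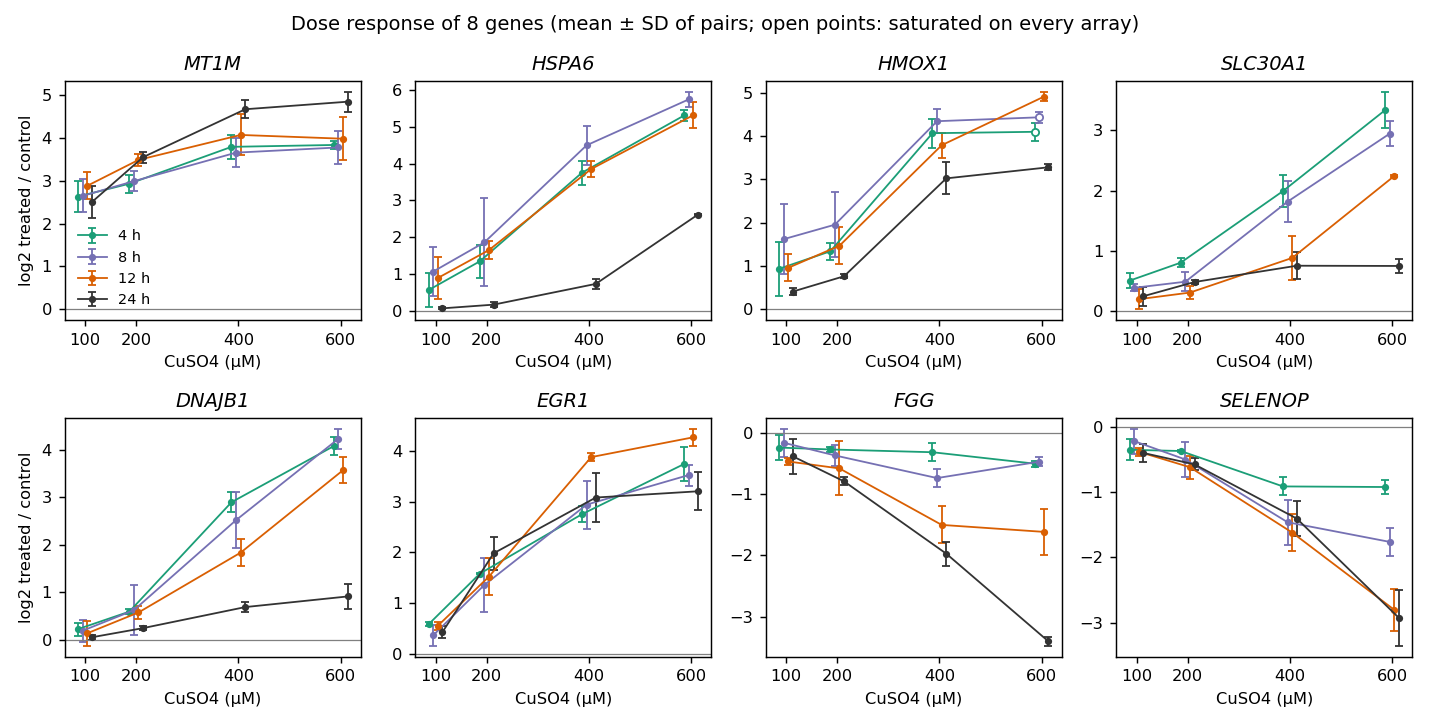
Log2 treated over control against copper dose (µM) at 4, 8, 12 and 24 h for MT1M, HSPA6, HMOX1, SLC30A1, DNAJB1, EGR1, FGG and SELENOP; points are means over pairs and bars the SD, with open points where the treated spot was saturated on every array. HSPA6 reached 5.74 at 600 µM for 8 h, and FGG reached -3.40 at 600 µM for 24 h.

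At 600 µM for 4 h chaperone genes led the rises. HSPA6 rose by 5.31 ± 0.14 on the log2 scale (n = 3), HSPA1L by 4.66 ± 0.16 (n = 3) and DNAJB1, the main HSP40 of the cytosol, by 4.08 ± 0.19 (n = 2). HSPH1 rose by 3.25 ± 0.21 and BAG3 by 3.05 ± 0.17 (n = 3 each), and HSPA1A, saturated at its brighter probe on all 6 arrays, was at 4.70 at its dimmer probe. Stress signalling genes rose beside them: the phosphatase DUSP1 by 4.21 ± 0.41 (n = 2), the transcription factor ATF3 by 4.12 ± 0.13 and IER5 by 4.11 ± 0.29 (n = 3 each). HMOX1 was at least 17.1-fold higher with its treated spot saturated on all 6 arrays (adjusted p = 4.65e-19), and SLC30A1 rose by 3.34 ± 0.30. In number, 12 of 29 heat shock genes rose and 17 were not called (camera adjusted p = 7.28e-13), 15 of 23 immediate early genes rose (5.1e-18) and 11 of 25 ATF4 genes (4.48e-21), among them SESN2 at 3.76 ± 0.19 and TRIB3 at 2.70 ± 0.051. NRF2 genes rose in number 7 of 29 (3.46e-11), with SRXN1 at 2.56 ± 0.035, metallothioneins 9 of 11 (7.43e-09), with MT1M at 3.84 ± 0.097, and inflammatory genes 5 of 18 (3.24e-07), with the chemokine CXCL8 at 3.52 ± 0.39. In the DNA replication list 2 of 32 fell, PCNA at -1.13 ± 0.062 and FEN1 at -1.14 ± 0.15 (1.79e-09). These counts were the same adjusted over the list alone. The falls were led by TMEM177, a mitochondrial membrane protein, which fell by 1.93 ± 0.23, the pigment granule gene HPS6, which fell by 1.91 ± 0.28, the kinase SGK1, which fell by 1.85 ± 0.10, and TMEM121, which fell by 1.72 ± 0.095. Limma called 246 genes higher and 47 lower. The authors' processed values gave 390 and 198, the scanner's log ratios 437 and 193, and median centring without loess 197 and 92. With day as a block 381 genes passed, of which 272 were shared. Within the one day that held all 3 pairs it was 293, from the same pairs, so that count does not test day.

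At 600 µM for 8 h HSPA6 rose by 5.74 ± 0.20 (n = 3), HSPA1L by 4.70 ± 0.16 and HMOX1 at least 21.6-fold, saturated on all 6 arrays (adjusted p = 2.71e-20). IER5 rose by 4.34 ± 0.25, DNAJB1 by 4.24 ± 0.22, CRYAB by 4.13 ± 0.34, CXCL8 by 4.11 ± 0.34 and the nuclear receptor NR4A1 by 4.04 ± 0.21. EPO fell by 2.03 ± 0.18, KANK1, a regulator of actin, fell by 1.84 ± 0.40 (n = 2), SELENOP fell by 1.76 ± 0.21 (n = 2) and the RNase P subunit gene POP7 fell by 1.70 ± 0.26. Of 29 heat shock genes 17 rose (camera adjusted p = 1.66e-11), and HSP90AA1 and DNAJB6 were among them, DNAJB6 at 3.22 ± 0.10. Immediate early genes rose in number 13 of 23 (1.24e-10), NRF2 genes 10 of 29 (3.33e-07, adjusted p = 0.0508 with an estimated correlation), ATF4 genes 9 of 25 (1.29e-09, adjusted p = 0.0706 with an estimated correlation) and metallothioneins 9 of 11 (3.8e-06, adjusted p = 0.0713 with an estimated correlation). Proteasome subunits rose in number 4 of 31, PSMD2 by 1.19 ± 0.18 and PSMD12 by 1.79 ± 0.17 among them, the latter at 0.65 at its dimmer probe (3.5e-06, adjusted p = 0.11 with an estimated correlation). In the mitosis list 6 of 30 fell, among them CENPF at -1.62 ± 0.031 and CCNB1 at -1.4 ± 0.28 (1.95e-12, adjusted p = 0.0508 with an estimated correlation). In the DNA replication list 3 of 32 fell, MCM3 the furthest at -1.44 ± 0.076 (3.59e-08). Each count was the same adjusted over the list alone. Limma called 295 genes higher and 170 lower, against 422 and 430 from the authors' processed values and 458 and 401 from the scanner's log ratios. All 8 h arrays of the 4 doses came from one day, so day could not add to the 8 h differences between doses.

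At 600 µM for 12 h secreted proteases were among the largest rises. The collagenase MMP1 rose by 5.01 ± 0.62 (n = 3), MMP3 by 4.60 ± 0.46 and the small GTPase RRAD by 5.17 ± 0.40, beside HSPA6 at 5.31 ± 0.35, HSPA1L at 4.92 ± 0.30, HMOX1 at 4.91 ± 0.11 (saturated on 3 of 6 arrays), CRYAB at 4.78 ± 0.28 and EGR1 at 4.27 ± 0.17. SELENOP fell by 2.80 ± 0.32, the phospholipase gene PLA2G12B fell by 2.38 ± 0.12, EPO fell by 2.27 ± 0.16 and HP, the hemoglobin-binding plasma protein haptoglobin, fell by 2.11 ± 0.29. Immediate early genes rose in number 16 of 23 (camera adjusted p = 8.14e-12), with FOS at 4.17 ± 0.67, and heat shock genes 15 of 29 (3.37e-10). NRF2 genes rose in number 13 of 29, with GCLM at 3.38 ± 0.093 (7.74e-07, adjusted p = 0.0585 with an estimated correlation), ATF4 genes 9 of 25 with 1 lower (9.03e-07, adjusted p = 0.144 with an estimated correlation), metallothioneins 9 of 11 (1.11e-05, adjusted p = 0.0848 with an estimated correlation) and proteasome subunits 8 of 31, with PSMD2 at 1.42 ± 0.015 (1.39e-08, adjusted p = 0.0517 with an estimated correlation). Inflammatory genes rose in number 6 of 18 (2.6e-05). Of 34 secreted liver proteins 9 fell (1.67e-06) and of 36 liver enzymes and transcription factors 4 fell (0.0165), among them CEBPA, a regulator of hepatocyte identity, at -1.55 ± 0.35. Mitosis genes fell in number 6 of 30, CENPF at -1.52 ± 0.25 (1.04e-09, adjusted p = 0.0878 with an estimated correlation), and DNA replication genes 2 of 32, MCM3 at -1.54 ± 0.12 and TYMS at -1.46 ± 0.20 (8.06e-07). The counts adjusted over the list alone were the same. Limma called 511 genes higher and 294 lower, against 864 and 793 from the authors' processed values, 959 and 782 from the scanner's log ratios and 338 and 752 with median centring without loess. The day block gave 804 genes, 720 of them shared. All 3 pairs lay within one day (805), so that count does not test day.

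At 600 µM for 24 h metallothioneins led the rises and liver genes the falls. MT1F rose by 4.98 ± 0.35 (n = 3), MT1M by 4.85 ± 0.23 (2.86 at its dimmer probe), MT1E by 4.52 ± 0.28 and MT1H by 4.18 ± 0.022. MT1G was at least 17.7-fold higher and MT1B at least 17.4-fold, both saturated on all 6 arrays (adjusted p = 1.26e-20 and 4.38e-21). CRYAB rose by 4.08 ± 0.18 and RRAD by 4.02 ± 0.39. FGG fell by 3.40 ± 0.073, SELENOP fell by 2.93 ± 0.43, HP fell by 2.70 ± 0.30 and the fatty acid carrier gene FABP1 fell by 2.60 ± 0.34. TMT1A fell by 2.77 ± 0.15 at its brighter probe and was at -0.16 at its dimmer one. In the secreted liver list 13 of 34 genes fell (camera adjusted p = 4.65e-13), among them FGA at -2.34 ± 0.33, APOH at -1.95 ± 0.097 and APOC3 at -1.90 ± 0.12. Liver enzymes and transcription factors fell in number 8 of 36 (0.00973), with CEBPA at -2.09 ± 0.14, and 11 of 25 genes of cholesterol synthesis and uptake fell (2.95e-08), among them SQLE at -1.77 ± 0.14. Cholesterol genes differed in their course at this dose. HMGCS1 was at 1.48, 2.19 and 2.01 at 4, 8 and 12 h (0.96, 0.95 and 1.27 at its dimmer probe) and at -0.64 at 24 h. ACAT2 was at -0.30, -0.75, -0.99 and -1.26 at the 4 times. For HMGCS1 the difference between 24 h and 4 h thus holds an early rise. Chaperones of the endoplasmic reticulum fell in number 3 of 18 (3.27e-07), PDIA4 the furthest at -1.21 ± 0.20. Mitosis genes fell in number 8 of 30, TOP2A the furthest at -1.38 ± 0.44 (2.23e-10, adjusted p = 0.0769 with an estimated correlation). Rises numbered 9 of 11 metallothioneins (4.17e-08), 14 of 23 immediate early genes (2.03e-09), 7 of 29 NRF2 genes (1e-07), 4 of 29 heat shock genes (0.919, not called) and 8 of 25 ATF4 genes (2.8e-10, adjusted p = 0.06 with an estimated correlation). Each count adjusted over the list alone equalled its count. Limma called 290 genes higher and 242 lower, against 570 and 552 from the authors' processed values, 610 and 550 from the scanner's log ratios and 242 and 335 with median centring without loess. With day as a block 497 genes passed, 475 of them shared, and within a day with 2 pairs 528, of which 481 were shared.

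The remaining lists at 600 µM held few calls. Of 20 zinc transporters SLC30A1 alone rose, by 2.95 ± 0.21 at 8 h and 2.25 ± 0.011 at 12 h, and it stood at 0.75 ± 0.11 at 24 h. Against control that list passed camera only at 400 µM for 12 h, as lower (0.0427, adjusted p = 0.0848 with an estimated correlation). Among 19 genes of copper uptake, export and chaperones, MTF1, the metal-sensing transcription factor, rose by 1.33 ± 0.28 at 12 h and the copper-carrying ferroxidase CP fell by 1.35 ± 0.20 at 24 h, and the list was called at no dose and time. Of 15 iron genes SLC40A1 rose by 1.39 ± 0.026 and HAMP fell by 1.16 ± 0.31 at 24 h. The iron list had a camera adjusted p of 0.0141 at 400 µM for 4 h, 0.0158 at 400 µM for 8 h (adjusted p = 0.05 with an estimated correlation) and 0.038 at 600 µM for 8 h (adjusted p = 0.0858 with an estimated correlation at the latter). Of 28 hypoxia and glycolysis genes 2, 2, 5 and 4 rose at 4, 8, 12 and 24 h, and ADM, a vessel-dilating peptide, was at 3.14 ± 0.22 at 4 h, while 1 fell at 24 h and the list was not called at this dose. Of 22 p53 targets 4, 3, 5 and 2 rose and 1 fell at 12 h, with GADD45A at 2.10 ± 0.015 (n = 2) at 4 h, and of 24 apoptosis regulators 2, 3, 3 and 0 rose, neither list being called at 600 µM. These counts rest on each gene's brighter probe. BBC3 was at 0.12, -0.08, 0.15 and 0.22 at that probe and at 1.27, 1.29, 0.9 and 0.55 at its dimmer one. TNFRSF10B was at 0.39, 0.34, 0.38 and 0.27 and, at its dimmer probe, at 1.46, 1.37, 1.26 and 0.26. The dimmer probes were not tested. Of 16 fatty acid genes 1, 2, 2 and 1 rose and 0, 1, 1 and 1 fell. That list was not called at 600 µM and was higher with both correlations at 200 µM for 8 h (0.00191) and 24 h (0.0019). Of 23 histone genes 2 rose at 8 h, 3 at 12 h and 2 at 24 h, and 1 fell at each of these times. Among those that rose was H2AC8 at 2.13 ± 0.34 at 12 h (camera adjusted p = 0.00628, adjusted p = 0.468 with an estimated correlation) and 1.54 ± 0.21 at 24 h (0.00019, adjusted p = 0.309 with an estimated correlation). Of 12 genes of protein lipoylation, GCSH fell by 1.22 ± 0.24 at 24 h, and the list was not called. In the list of 19 genes of mitochondrial complex IV 0 were called, and the list's camera adjusted p of 0.0147 at 8 h was not kept (adjusted p = 0.311 with an estimated correlation). Calls numbered 0 of 42 ribosomal protein genes, 0 of 16 stromal markers and 0 of 19 blood markers, and none of these 3 lists was called at 600 µM. RPLP1 was at 0.06, -0.14, 0.02 and 0.02 at 4, 8, 12 and 24 h at its brighter probe, which was counted. Its dimmer probe was at 1.61, 1.15, 2.25 and 1.69. Over the lists and groups camera called 182 of 416 tests, 121 higher and 61 lower, of which 90 (69 higher, 21 lower) held with an estimated correlation. The authors' processed values gave 110 higher and 89 lower, and day as a block 175 calls. The counts adjusted over the list alone were the same here.

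**Figure D3:**
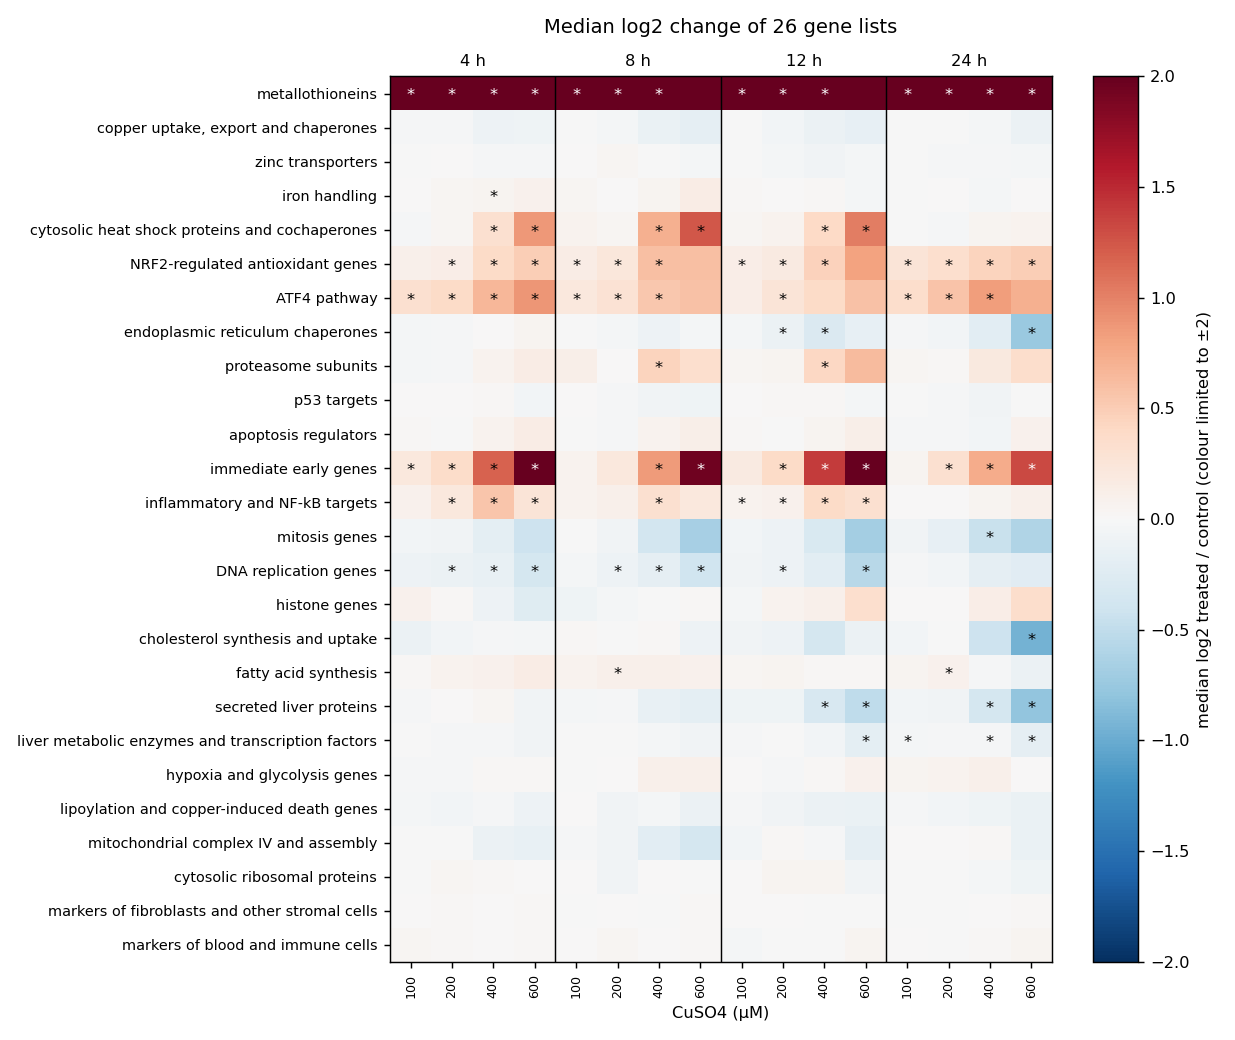
Median log2 treated over control of the members of each of 26 gene lists in the 16 groups of dose (µM) and time (h), with the colour limited to the range from -2 to 2 and a star where camera called the list with both a preset and an estimated correlation. Metallothioneins reached a median of 4.12 and cholesterol genes one of -0.95 at 600 µM for 24 h.

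Dose trends were fitted as a slope from 100 to 600 µM and are given as the fitted change over that range. HSPA6 gained 4.89 at 4 h and 4.89 at 8 h, HSPA1L 4.45 and 4.43, DNAJB1 4.12 at 4 h and IER5 4.29 at 8 h. At 12 h MMP1 gained 4.99, RRAD 4.97 and MMP3 4.58, and at 24 h RRAD gained 4.00, CRYAB 3.90 and HSPA1A 3.66 (its dimmer probe was at -0.06 at 100 µM and 1.79 at 600 µM). Trends went down for SOX9, a developmental transcription factor (-1.83), HPS6 (-1.81) and TMEM177 (-1.77) at 4 h, and for KANK1 (-1.82), EPO (-1.75) and SAA4 (-1.68) at 8 h. They went down for SELENOP (-2.47) and PLA2G12B (-2.26) at 12 h, and for FGG (-3.04) and HP (-2.62) at 24 h. Limma called 182 upward and 30 downward trends at 4 h, 265 and 149 at 8 h, 429 and 227 at 12 h, and 242 and 204 at 24 h. The authors' processed values gave 287 and 122 at 4 h, 399 and 390 at 8 h, 721 and 632 at 12 h, and 459 and 422 at 24 h. The scanner's log ratios gave 332 and 120 at 4 h, 436 and 428 at 8 h, 856 and 618 at 12 h, and 529 and 449 at 24 h, and median centring without loess gave 312 and 440 at 12 h and 215 and 262 at 24 h. The day block gave 656 trends at 12 h (599 shared) and 439 at 24 h (416 shared). Its 414 trends at 8 h do not test day, since all 8 h arrays came from one day. At 4 h day could enter only as a random block, with 212 trends. HSPA1A at 600 µM was saturated on every treated spot at 4, 8 and 12 h, which bounds its values there from below.

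The response at 24 h was set against that at 4 h within each dose. At 600 µM the cancer-testis genes VCX3A and VCX were higher at 24 h than at 4 h by 2.68 and 2.56 in log2 response, MMP1 by 2.68, RRAD by 2.47 and the imprinted gene PHLDA2 by 1.77. DNAJB1 differed by -3.17, FGG by -2.90, DUSP1 by -2.88 and SLC30A1 by -2.58. HSPH1 differed by -2.47, HSP90AA1 by -2.13, and the cholesterol genes MSMO1 and SQLE by -2.30 and -1.67. DUSP1 at 24 h lost its own call against control without the first pair, at 0.93. By lists at 600 µM, counted over members complete in all pairs, heat shock genes shifted by a median of -1.22 (10 of 17 lower), cholesterol genes by -0.93 (9 of 20), secreted liver proteins by -0.67 (9 of 25), chaperones of the endoplasmic reticulum by -0.53 (2 of 16) and zinc transporters by -0.13 (1 of 18), all past camera with an estimated correlation too. Other lists passed camera at the preset correlation alone. Metallothioneins shifted by 0.83 (camera adjusted p = 0.0273, adjusted p = 0.393 with an estimated correlation), histone genes by 0.57 (8.29e-09, adjusted p = 0.123 with an estimated correlation), proteasome subunits by 0.20 (0.000129, adjusted p = 0.207 with an estimated correlation), ATF4 genes by -0.32 (0.000266, adjusted p = 0.273 with an estimated correlation) and immediate early genes by -0.46 (0.000773, adjusted p = 0.207 with an estimated correlation). The inflammatory (0.0149), mitosis (0.0326) and DNA replication (0.0326) lists also passed at the preset correlation and not with an estimated one. At 400 µM HSPA6 differed by -3.02 and HSPA1L by -2.44, while PHLDA2 was higher at 24 h by 1.44. HSPA1A was called lower at -2.35, not an exact size, since it was saturated on 7 of 8 arrays at 4 h, and its dimmer probe was at 3.27 at 4 h and 0.21 at 24 h. MT2A was called at 1.44 at 400 µM. At 200 µM MT2A alone was called, at 1.25 (adjusted p = 0.0246), and no longer when any one pair was left out (0 genes), with its value then still between 1.2 and 1.29. MT2A was saturated in the treated channel on every array at 200 and 400 µM at both times, so neither value is an exact difference in response, and both went with the control channel, whose mean log2 level at 200 µM was 14.7 at 4 h and 13.54 at 24 h. For MT1F at 600 µM the control level was 11.01 at 4 h and 10.26 at 24 h and the treated level 15.06 and 15.24. Limma called 145 genes higher and 222 lower at 600 µM, 30 and 33 at 400 µM, 1 at 200 µM (570 at an unadjusted p under 0.05) and 0 at 100 µM (331 at an unadjusted p under 0.05). At 600 µM the authors' processed values gave 382 and 406 and the scanner's log ratios 404 and 439. At 400 µM the authors' processed values gave 89 and 61 and the scanner's log ratios 96 and 68, and at 200 µM 2 and 3 and 1 and 2. With day as a fixed block 390 genes differed at 600 µM, 275 of them shared, and at 200 µM 1 gene, lower and not shared. At 400 µM a random block gave 61. No day held both 4 h and 24 h arrays, so no value within a day could be had, and the 2 times were linked through a single pair of 200 µM for 12 h.

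**Figure D4:**
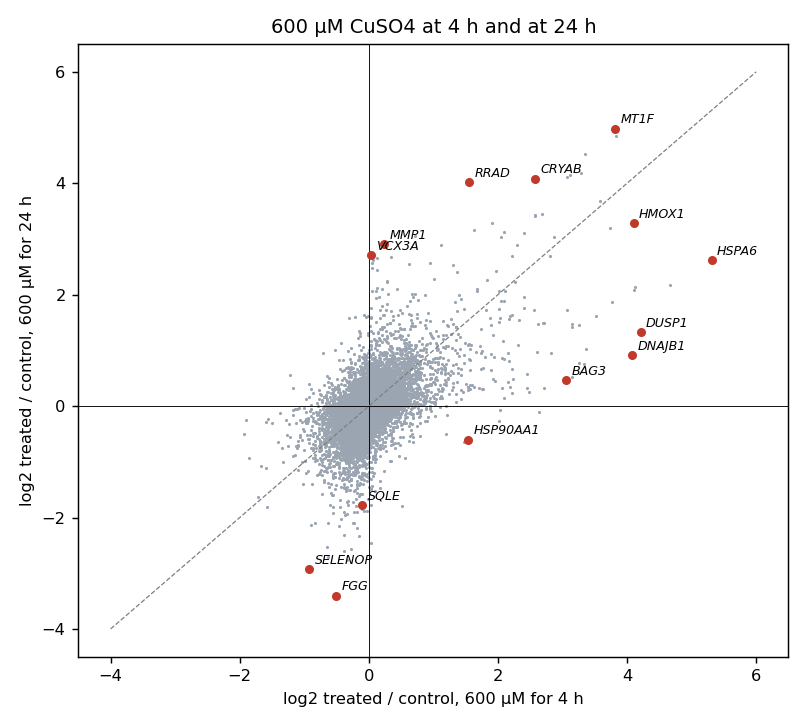
Log2 treated over control at 24 h against that at 4 h for each gene at 600 µM, with 14 genes labelled and the dashed line marking equal values; each point is the mean over pairs. DNAJB1, DUSP1 and BAG3 lie below the line, and MMP1, RRAD and VCX3A above it.

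The dose trend itself differed between 24 h and 4 h for keratin-associated KRTAP3-1 (2.62), MMP1 (2.60) and RRAD (2.57) upward and for DNAJB1 (-3.24), FGG (-2.79) and BAG3 (-2.75) downward. SLC30A1 differed by -2.39, MSMO1 by -2.40 and CEBPA by -1.49. Limma called 150 genes with a higher and 223 with a lower trend at 24 h, against 363 and 412 from the authors' processed values and 415 and 457 from the scanner's log ratios. A fixed block for day could not be fitted here, and a random block gave 372.

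Genes called at 600 µM at both 4 h and 24 h in one direction numbered 116, 108 higher and 8 lower, and HSPA6, HMOX1, ATF3 and EGR1 were among the higher ones. Independent lists of these sizes would share 3.88 higher and 0.619 lower genes. In 10 simulations with unchanged groups and a shared control, 2.2 genes were shared on average and 4 at most. The control's deviation was given the spread of a pair, which need not be its real one. The simulations therefore do not decide how much a shared control adds. If one control pool served all arrays, part of the overlap may come from it. The authors' processed values gave 173 higher and 45 lower, the scanner's log ratios 190 and 43, and median centring without loess 89 and 19. Over the 16 groups 1205 genes were called at least once, 694 higher, 511 lower and 0 in both directions by the limma test. A set of 13 genes, singled out after their values were seen, was higher in all 16 groups, among them MT1A, MT1B, MT1E, MT1F, MT1G, MT1H, MT1M, MT1X, the pseudogene MT1JP, ASNS, INKA2 and the transcript BC007034.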

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

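The tests of the day of image extraction below were chosen after the result was seen, and the other tests of this part before. No group of 4 pairs held a sample far from the others in the 12 genes tested (0 found).

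Responses that differed between 24 h and 4 h were picked out because the difference itself was tested in limma. At 600 µM 367 genes differed, led upward by VCX3A (2.68), MMP1 (2.68) and VCX (2.56) and downward by DNAJB1 (-3.17), FGG (-2.90) and DUSP1 (-2.88). At 400 µM 63 genes differed, with PHLDA2 (1.44), MT2A (1.44) and CACNA2D4 (1.39) called higher at 24 h and HSPA6 (-3.02), HSPA1L (-2.44) and HSPA1A (-2.35) lower. HSPA1A was saturated on 7 of 8 arrays at 4 h, so its size is not exact, and its dimmer probe was at 3.27 at 4 h and 0.21 at 24 h. CACNA2D4 lost its call with the mean of its probes (0.82). At 200 µM 1 gene was called, MT2A (1.25), and no longer without any one pair (0 genes), at 1.2 to 1.29. At 200 and 400 µM MT2A was saturated in the treated channel on every array at both times, and its differences went with the control level (14.7 at 4 h and 13.54 at 24 h at 200 µM), so they are not exact response differences. At 100 µM 0 genes were called by limma (331 at an unadjusted p under 0.05). The dose trend differed for 373 genes, KRTAP3-1 (2.62), MMP1 (2.60) and RRAD (2.57) upward and DNAJB1 (-3.24), FGG (-2.79) and BAG3 (-2.75) downward.

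Other ways to divide the pairs show what chance gives. For the difference at 400 µM, 1 of the 35 splits of the pairs, the real one, gave as many genes (63 against at most 23 in the others). This counts 4 pairs at 400 µM for 4 h, where the protocols state 3 sets of RNA. If 1 pair repeats a set, 10 splits remain, so chance is not excluded there. At 100, 200 and 600 µM the 10 splits are too few for a share under 0.05. As many genes came from 10, 1 and 1 of them, with real counts of 0, 1 and 367 and at most 0, 0 and 3 in the others. For the trends, 1 of 100 assignments of doses to pairs, the real one, gave as many genes at each time. The counts were 212 against at most 130 at 4 h, 414 against 329 at 8 h, 656 against 234 at 12 h and 446 against 242 at 24 h. A random assignment of doses to these pairs thus rarely gives such counts. Chance differences between cultures are not excluded, since the pairs may be technical replicates. At 4 h dose also went with day, as the 400 µM arrays came from days of their own. For the difference of trends 1 of 100 assignments of times gave as many (373 against at most 360). The 9 draws that kept the 600 µM pairs of a time together reached 360 and the 90 that mixed them at most 2, which points to the 600 µM groups as the structure behind the count.

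The 4 h and 24 h arrays were extracted on different days, so day may contribute to the 600 µM difference. With day as a fixed block 275 of the 367 genes stayed called in the same direction, but 1 pair of 200 µM for 12 h alone links the days, so this does not decide. A shift per gene with the day, alike at every dose, is argued against as the whole cause. On the same 2 days, with 3 pairs per dose at 4 h and 2 at 24 h, 1 of 366 genes reached at 100 µM at least a share of 0.5 of its 600 µM difference, and the median was 0.07 (quartiles 0.01 and 0.15) against 1.27 at 600 µM. A day effect that grows with the response stays open. The labels leave unclear whether one pool or time-matched cells were the control. A control that differed between the times, alike at every dose, is argued against as the whole cause by the same values at 100 µM, for these genes as a set. A part played by the control stays open, also for MT2A, whose control level differed between the times. The biological explanation the design names, a longer exposure, was not tested apart from day and control.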

How the results depend on the processing

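No named gene, and no list at 600 µM, was called in the opposite direction under any alternative. Lists at the lower doses were not compared for direction in this way. The larger direction turned in 13 of 415 recomputed counts. Median centring without loess turned 123 higher and 33 lower into 89 and 93 at 400 µM for 12 h, 511 and 294 into 338 and 752 at 600 µM for 12 h, and 290 and 242 into 242 and 335 at 24 h. It turned 429 and 227 into 312 and 440 for the 12 h trend, 242 and 204 into 215 and 262 for the 24 h trend, and 30 and 33 into 36 and 29 for the time difference at 400 µM. The authors' processed values turned 295 and 170 into 422 and 430 at 600 µM for 8 h, and they and the scanner's log ratios turned the time difference at 400 µM into 89 and 61 and into 96 and 68. The time difference at 200 µM went from 1 gene higher to 1 lower with day as a fixed block. Of the 415 counts 364 stayed within 1.5 times of the reported count and 51 moved. The scanner's log ratios gave 630 genes at 600 µM for 4 h, 24, 36, 216 and 859 at 100, 200, 400 and 600 µM for 8 h, 41, 352 and 1741 at 200, 400 and 600 µM for 12 h, and 411 and 1160 at 400 and 600 µM for 24 h. They gave 452, 864, 1474 and 978 trends at 4, 8, 12 and 24 h, 3, 164 and 843 differences between 24 h and 4 h at 200, 400 and 600 µM, 872 differences of trends and an overlap of 233. The authors' processed values gave 27, 39, 161 and 588 genes at 4 h in order of dose, 26, 41, 251 and 852 at 8 h, 26, 44, 323 and 1657 at 12 h, and 29, 391 and 1122 at 200, 400 and 600 µM for 24 h. They gave 409, 789, 1353 and 881 trends, 5, 150 and 788 time differences at 200, 400 and 600 µM, 775 differences of trends and an overlap of 218. The time difference at 200 µM, 1 gene, became 3 with pairs rotated by 1, 2 with pairs rotated by 2, 2 with single arrays, and 0 with either dye orientation alone or day as a random block (limma, 570 genes at an unadjusted p under 0.05). At 100 µM for 4 h day as a fixed block gave 10, and with an estimated correlation 90 list calls remained. Leaving out each pair in turn gave 0 to 0 genes for the time difference at 200 µM and 146 to 245 at 400 µM for 24 h, the highest without the second pair. The cause was not tested.

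The pair number as a block within each time gave 214, 414, 654 and 446 trends and 373 differences of trends, and within each dose 0, 1, 70 and 367 time differences, so it changed no call count by over 1.5 times. The labels do not state whether pairs of one number share more than the number. Of 72 comparisons between doses of one time 35 correlated above 0.1, against 52 of 153 between pairs of different number. Of 12 comparisons between 4 h and 24 h 5 did, against 6 of 27. A source shared by pairs of one number is therefore not excluded. Without the 400 µM groups, tried after the data were seen, 231 trends at 4 h and 391 differences of trends were called. Day as a fixed block could not be fitted for the 4 h trend, the time difference at 400 µM and the difference of trends. Signal over background limits what dim probes show, as the share of probes well above background in a channel went down to 74.7% on one array, and saturation limits the brightest ones.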

Other observations

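Some genes outside the largest changes had courses of their own at 600 µM. ELOVL5, a fatty acid elongase, rose by 1.70 ± 0.010 (n = 3) at 8 h and by 1.86 ± 0.27 at 12 h and stood at -0.01 ± 0.24 at 24 h. The glycolytic enzymes HK1 and PFKP rose by 1.29 ± 0.037 and 1.36 ± 0.23 at 12 h and by 1.64 ± 0.26 and 1.65 ± 0.17 at 24 h. HERPUD1, a gene of the unfolded protein response, rose by 1.44 ± 0.034 at 4 h and was at 0.28 ± 0.40 at 24 h. SDF2L1, another such gene, fell by 1.51 ± 0.094 at 8 h.

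MCL1, which blocks apoptosis, rose by 2.72 ± 0.19 at 8 h and by 2.01 ± 0.033 at 12 h, while PMAIP1 and HRK, which promote it, rose by 2.27 ± 0.041 and 1.84 ± 0.25 at 12 h. VEGFA, a growth factor for vessels, rose by 1.13 ± 0.039 at 4 h and 1.35 ± 0.18 at 12 h, and ADM by 3.29 ± 0.22 at 8 h and 2.97 ± 0.15 at 12 h. CYP1A1, a detoxifying enzyme, fell by 1.22 ± 0.16 at 4 h.

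In the tests below, which probes count as metallothioneins and how the spread of the dye result is read were settled after the values were seen, while the tests were written before.

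A set of 4 probes not named as metallothioneins, among them those of ASNS, INKA2 and BC007034, rose in all 16 groups together with the metallothioneins. They were set apart by name alone. BC007034 has no gene symbol here, so whether it is itself a metallothionein transcript was not checked. At 600 µM for 24 h these 3 were at 3.12, 3.43 and 3.29, and over pairs they correlated with the mean metallothionein at 0.912, 0.835 and 0.798. Signal from neighbouring spots is argued against, since 0 of the 4 probes had a neighbour raised 2-fold or more. Metallothionein RNA binding to these probes may explain part of the pattern and stays open. The metallothionein gains it is set against are not exact, since MT1G and MT1B were saturated on every array at 600 µM for 24 h. The 4 probes gained a median of 0.95 from 4 h to 24 h, inside the metallothioneins' range of 0.70 to 1.17, but the gain of BC007034 alone, 1.37, lay outside it. With MT1JP counted among them, as at first, the verdict was the same. If BC007034 is a metallothionein transcript, its gain does not bear on such binding.

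At 100 µM for 8 h arrays of opposite dye ran weakly against each other, with a median correlation across probes of -0.189, and of -0.206 at 200 µM for 8 h. Arrays of one orientation had medians of 0.542 and 0.547 in these groups, with lowest values of 0.236 and 0.389. A dye effect per gene shared with the other times may be the source. Once it was removed the median at 100 µM for 8 h, here taken across genes, was -0.10 against -0.20 before. The 9 combinations lay between -0.673 and 0.185, so the test does not decide. It was read by this spread only after the value was seen, since the median alone lay at or below 0. Each group held both orientations in equal number, so such an effect cancels in the group means.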
